A study of Homo sapiens with 2 samples.

How the data were processed

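Human adipose-derived stromal cells were profiled on 2 Affymetrix Human Genome U133 Plus 2.0 arrays, 1 of uninduced and 1 of adipogenic induced cells. Per the labels' protocols, confluent cells received 0.5 mM isobutylmethylxanthine, 5 µM rosiglitazone, 1 µM dexamethasone and 1 µM insulin in medium with 3% fetal bovine serum for 3 days, and then the same medium without isobutylmethylxanthine and rosiglitazone. RNA was taken 9 days after confluence. The series text speaks of cells from 3 donors, and whether an array holds RNA of 1 donor or a pool is not given in the sources used here. A difference between the arrays can therefore come from the induction, the donors, the cultures or the arrays.

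The deposited values are linear signal intensities, 1 per probe set, on 1-colour arrays. Per the labels' protocols the authors extracted them with GeneChip Operating Software version 1.2, scaled each array globally to a target of 2500, and used Data Mining Tool version 3 for their own calls, which were not used here. The mean signal after trimming 2% at each end was 2499.6 in both arrays. Ratios between the arrays are therefore relative to this trimmed mean, and a shift shared by most transcripts would not show.

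Gene names came from the platform annotation, which can be old. Of 54675 probe sets 41097 had 1 gene symbol, 1801 several and 11777 none, the last including most control probe sets. Control probe sets for GAPDH and ACTB carried a gene symbol and were used as gene probe sets. A control probe set thus represented GAPDH in the housekeeping list. Symbols were updated through gene identifiers, which matched for 41043 probe sets and altered 0 symbols. Probe sets with several symbols or none were not named, and 59 probe sets of sex-linked genes that bear on a donor were left out. A gene was represented by its probe set with the highest mean log2 signal, and the text says where other probe sets of a named gene above the floor had the opposite sign, which was so for 12 of the 99 named genes.

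Signals were raised to a floor, the median of their array, before the log2 ratio of induced over uninduced was taken. A gene was kept if at least 1 signal exceeded its floor. Where the weaker signal lay under the floor, the fold is a lower bound. The floor stood in for detection calls, which were not used here. Of 54 signals of 27 bacterial poly-A control probe sets, 52 lay under the floor, with a median of 133 and a highest value of 1028. The 18 hybridization spike probe sets had a mean log2 ratio of -0.002 with an SD of 0.12, from -0.20 to 0.26, which shows how closely the arrays matched in hybridization and not how cultures vary. The ratio of 3' to 5' signal was 1.07 and 1.11 for GAPDH and 1.86 and 1.502 for ACTB, in the uninduced and the induced array. The result of 1 further set of control probe sets is not reported here.

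With 1 array per group no test was run and no p-value was computed. Genes at least 2-fold apart were counted. For each list the median log2 ratio of its measured members was placed among 10000 random lists of equal size drawn from the same 20 bins of mean log2 signal. This percentile describes these arrays and says nothing about other cultures. The range leaves out 2.5% of the random lists at each end, so about 5% of lists of randomly drawn genes lie outside it. Random members were drawn independently, whereas genes of a real list can vary together. The 5% is therefore not a chance rate for the lists used here. The grouping, the 24 lists, the rule for named genes and the alternatives were set before the data were examined, except where the text says otherwise. The lists hold adipogenic, lipid, hormone response, matrix, lineage, cell cycle, stress, clock, inflammatory, housekeeping and other cell type genes. Genes of a list that have no probe set with a single symbol were not analysed here. Named genes are the 10 highest and 10 lowest ratios, up to 4 members per list with the largest ratio of at least 2-fold (the largest 2 where fewer reach it), the flow cytometry panel and 7 textbook adipocyte genes.

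The steps were tested on a simulated pair of arrays with 13007 genes kept and 200 genes altered. Both simulated arrays came from the uninduced signals, with an assumed noise and no difference between cultures. The altered genes were drawn from genes above the floor before the change, so genes that rise from under the floor were not tested. The rates below hold for that noise and that choice of genes and are not error rates of the real arrays. Genes raised 4-fold and 16-fold were called in 100% of cases, genes lowered 4-fold in 82% and lowered 16-fold in 80%, and 0.05% of unaltered genes were called. Of 200 unaltered lists of 15 genes, 7.0% lay outside the range, and 100% of 100 lists raised by 0.5 on the log2 scale lay above it.

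Alternatives were median centring, quantile normalization, loess with a span of 0.3, floors at the 40th and 60th percentile, no floor, both signals above the floor, the mean over probe sets, removal of probe sets whose names mark binding to several transcripts, and size limits of 1.5-fold and 4-fold. Removing probe sets that can bind several transcripts also drops list members with no other probe set above the floor. Counting members under the floor in both arrays as 0 was added after the data were seen. Leaving out a replicate was not possible with 1 array per group. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.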

Results

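Messenger RNA was profiled in human adipose-derived stromal cells, the adherent, fibroblast-like cells that grow out of digested subcutaneous fat and that can form adipocytes in culture. The groups were uninduced cells and cells given an adipogenic hormone mixture, both taken 9 days after confluence, with 1 array per group. Each array gave a signal for 54675 probe sets, with a median of 594 in the uninduced and 607 in the induced array. Those medians served as floors, below which a signal was treated as unmeasured. Of 19740 named genes, 13373 had a signal above the floor in at least 1 array and 10991 in both. There were no replicate arrays, so no value below has a replicate error or a test, and the number of arrays limits the precision. The differences are between these 2 arrays, and "higher" and "lower" refer to the induced array relative to the uninduced one. The log2 ratios of probe sets of the same gene had a pooled SD of 0.48 over 5180 genes, a spread within this pair of arrays that holds no difference between cultures.

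The comparison asks which transcripts differ between stromal cells kept in adipogenic conditions and cells left uninduced. Genes were ranked with signals raised to the floor, so the order of those given as "at least" is not known. The signal of LPL, the lipase that frees fatty acids from circulating triglyceride, was 336 in the uninduced and 113730 in the induced array, at least 192-fold higher. ADIPOQ, which encodes the adipocyte hormone adiponectin, was at least 92.9-fold higher, with signals of 25.4 and 55176. The lipid droplet coat genes PLIN4 and PLIN1 were at least 82.5-fold and at least 55.4-fold higher. FABP4, the fatty acid carrier of adipocytes, was 80.9-fold higher, with signals of 3122 and 252666. CIDEC, which enlarges lipid droplets, was 62.0-fold higher, DGAT2, which makes triglyceride, 54.6-fold, and GPD1, which supplies its glycerol backbone, at least 47.5-fold. CHI3L2, a chitinase-like secreted protein, was 55.1-fold higher, from an uninduced signal of 601, just above the floor. Bacterial poly-A control probe sets reached signals of up to 1028. Folds whose weaker signal lay below that, such as those of CHI3L2, DGAT2, RBP4 and LEP, are therefore closer to lower bounds. RBP4, the retinol carrier, was 74.8-fold higher by its brightest probe set, but its other probe set above the floor had a log2 ratio of 0.50.

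In all, 712 genes were at least 2-fold higher and 697 at least 2-fold lower, while 11964 differed by less. The uninduced signal lay under the floor for 191 of the higher genes, and the induced signal for 129 of the lower ones, so that their folds are bounds. Beyond 4-fold the counts were 145 higher and 49 lower, and beyond 16-fold 32 higher and 0 lower. Without the floor the 2-fold counts became 1346 higher and 1352 lower. Across the genes above the floor in both arrays the log2 signals had a Pearson correlation of 0.928, a figure across genes, which are not independent replicates.

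Among the 10 genes with the lowest ratios, ISLR, a secreted protein of mesenchymal cells, was 14.2-fold lower, with signals of 24598 and 1731. SFRP4, a secreted Wnt antagonist, was 13.3-fold lower, with signals of 63338 and 4765. The matrix-associated genes FNDC1 and MXRA5 were 13.0-fold and 11.4-fold lower. KLHDC7B was at least 10.96-fold lower and GUCY1A1, a subunit of the nitric oxide receptor, 10.03-fold. The induced signals of FNDC1 and GUCY1A1, 723 and 732, lay below the 1028 that poly-A controls reached. Their folds, and others with induced signals that weak, are therefore closer to lower bounds. The adhesion molecule NTM was 8.73-fold lower, the transcriptional regulator MN1 7.46-fold and the collagen receptor subunit ITGA11 7.32-fold. COL14A1 was 7.52-fold lower by its brightest probe set, whereas another of its probe sets had a log2 ratio of 0.40.

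**Figure D1:**
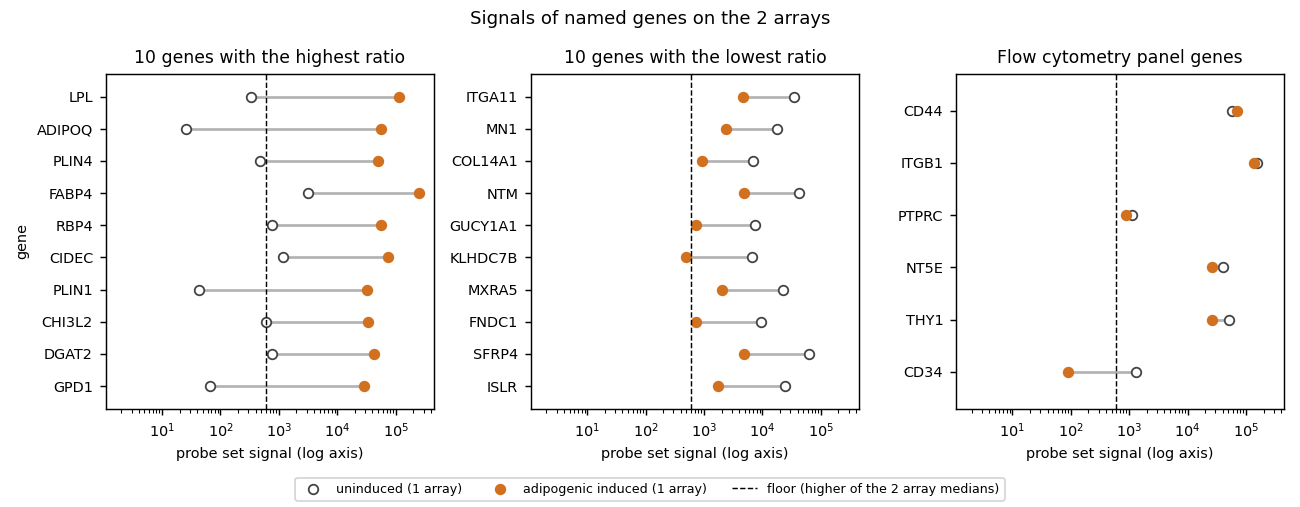
Probe set signal on a log axis for the 10 genes with the highest ratio after signals were raised to the floor, the 10 with the lowest and the 6 genes of the flow cytometry panel, with 1 open circle for the uninduced and 1 filled circle for the induced array. The dashed line marks the higher of the array medians; ADIPOQ lies far left of it in the uninduced array at 25.4, and CD34 in the induced array at 89.7.

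Gene lists fixed before the data were examined were described by the median log2 ratio of their measured members. Each median was placed among the medians of 10000 random lists of the same size and similar signal, and the range meant below leaves out the lowest 2.5% and the highest 2.5% of them. Of 24 lists, 11 had a median above that range, 4 below it and 9 inside it.

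In fatty acid and triglyceride synthesis and uptake, 20 of 23 measured genes were at least 2-fold higher and 0 were lower by that much, with a median log2 ratio of 3.13 against a range of -0.30 to 0.20, the highest median of the 24 lists. PCK1, which feeds glycerol synthesis, was at least 41.4-fold higher in the same list as LPL, DGAT2 and GPD1. Among genes of the lipid droplet coat and of lipolysis, 12 of 17 were higher and 0 lower by that measure, with a median of 1.39 against a range of -0.34 to 0.25. Cholesterol synthesis and uptake had 10 of 13 genes higher and 0 lower, with a median of 1.495 against a range of -0.39 to 0.27. INSIG1, which senses sterols, was 6.50-fold higher, MVD at least 6.20-fold and LSS 3.30-fold. IDI1 was 4.06-fold higher by a probe set that can bind several transcripts, and its other probe sets reached down to a log2 ratio of -0.63. Mitochondrial fatty acid oxidation had 6 of 18 genes higher and 0 lower at 2-fold, with a median of 0.80 against a range of -0.30 to 0.23. Of those 6, UCP2, an inner membrane carrier, was 6.78-fold higher and CS, of the tricarboxylic acid cycle, 2.03-fold. Neither is an enzyme of fatty acid oxidation. HADH was 5.67-fold higher, ACADS 2.99-fold and DECR1 2.28-fold. CPT1A, the only measured member below 0, had a log2 ratio of -0.84, with another probe set at 0.75. CS and CPT1A were named after their values had been seen.

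Adipokines and other secreted adipocyte proteins included 9 of 14 genes that were at least 2-fold higher and 1 that was lower, with a median of 2.25 against a range of -0.38 to 0.27. LEP, which encodes leptin, was 23.3-fold higher, with signals of 775 and 18085, and the apolipoprotein gene APOC1 33.9-fold higher. RARRES2 was the lower gene, at a log2 ratio of -1.38, and ANGPTL4 was at -0.78. Both were named after their values had been seen. Among adipogenic transcription factors, 5 of 17 were higher and 1 was lower. CEBPA, a master regulator of the adipocyte state, was at least 31.5-fold higher. PPARG, the nuclear receptor that rosiglitazone activates, was 6.37-fold higher, with signals of 1835 and 11695. The sterol-sensing receptor NR1H3 was 8.76-fold higher and KLF15 6.09-fold. ZNF423 was the lower gene, at a log2 ratio of -1.64, and was named after its value had been seen. The median of this list was 0.26 against a range of -0.35 to 0.24. It lay inside the range after quantile normalization, at 0.23, and under 5 further settings.

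Genes that respond to glucocorticoids, the class of the dexamethasone in the medium, included 8 of 17 that were higher and 0 that were lower, with a median of 0.86 against a range of -0.32 to 0.24. MAOA, a monoamine oxidase, was at least 26.2-fold higher, the receptor chaperone FKBP5 4.98-fold, the cortisone-activating enzyme HSD11B1 3.68-fold and ZBTB16 at least 3.56-fold. Insulin signalling and glucose handling had 4 of 16 genes higher and 1 lower, with a median of 0.56 against a range of -0.36 to 0.23. PDE3B, which breaks down cyclic AMP, was at least 4.66-fold higher, the glucose-phosphorylating HK2 4.47-fold, PFKFB3 3.22-fold and the growth factor binding protein IGFBP5 3.04-fold. IGF1 was the lower gene, at a log2 ratio of -1.22, and the glucose transporter SLC2A4 was under the floor in both arrays. Both were named after their values had been seen. Without probe sets that can bind several transcripts, the median of this list was 0.25, inside the range.

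Brown and beige adipocyte markers did not stand apart as a list. Of 9 measured genes 3 were at least 2-fold higher and 2 lower, and the median was -0.07, at percentile 38.5 of the random lists. KCNK3, a potassium channel, was at least 8.74-fold higher, CITED1 at least 3.52-fold and COX7A1 2.16-fold. EVA1A was 2.05-fold lower, but it is not an established marker of brown or beige adipocytes. The list's median was not recomputed without it. The remaining 5 members, which include UCP1, the heat-producing uncoupling protein, were under the floor in both arrays. UCP1 was named after its status had been seen.

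Fibrillar collagens and other extracellular matrix genes were lower as a list, with 6 of 22 at least 2-fold lower and 0 higher. Their median was -0.52 against a range of -0.25 to 0.19. BGN, a matrix proteoglycan, was 5.26-fold lower, POSTN 3.92-fold, the collagen chain COL5A1 2.77-fold and the crosslinking enzyme LOXL1 2.75-fold. The basement membrane list had a median of 0.25, inside its range. In it NID1 was 2.40-fold higher and HSPG2 2.95-fold lower. Matrix-degrading enzymes and their inhibitors went both ways, with 5 of 16 higher, 3 lower and a median of -0.23 inside the range. The inhibitor TIMP4 was 6.16-fold higher and the stromelysin MMP3 3.55-fold, whereas MMP16 was 5.07-fold lower. Another MMP16 probe set had a log2 ratio of only -0.18. MMP19 was 3.55-fold higher by 1 probe set, and its lowest one had a log2 ratio of -0.08. Contractile and myofibroblast genes had a median of -0.08, inside the range, with 3 of 17 higher and 1 lower. MYH11, a smooth muscle myosin, was 5.29-fold higher, ACTG2 2.18-fold and TGFB2 2.08-fold, and TGFBI was 3.18-fold lower. Other probe sets of MYH11 and TGFB2 had log2 ratios down to 0.34 and 0.09.

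The flow cytometry panel of the study covers surface proteins used to define stromal cells, and its 6 genes were compared on the arrays. CD34, a marker of freshly isolated stromal and of endothelial cells, had signals of 1288 in the uninduced and 89.7 in the induced array, at least 2.12-fold lower. THY1 had a log2 ratio of -0.98 and the leukocyte marker PTPRC of -0.32. ITGB1 had a log2 ratio of -0.20, NT5E of -0.61 and CD44 of 0.25, and in each of these the probe sets disagreed in sign. Over all 15 stromal surface markers 3 were lower and 0 higher at 2-fold. VCAM1 was 4.09-fold lower and PDGFRB 2.12-fold. The median, -0.32, lay at percentile 2.70, just inside the range, and below it under 4 settings, for example at -0.61 without the floor.

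Wnt pathway and preadipocyte factors included 7 of 19 genes that were at least 2-fold lower and 1 that was higher. Besides SFRP4, the receptor FZD7 was 5.28-fold lower, the ligand WNT2 3.59-fold and GATA2, a repressor of fat cell formation, 3.41-fold. Another GATA2 probe set had a log2 ratio of only -0.18. The median was -0.27, inside the range, and passed below it under 3 settings, for example at -0.37 when both signals had to be above the floor. Bone and cartilage lineage genes had 3 of 12 members lower and 0 higher, with a median of -0.28 inside the range. SOX9 was 2.20-fold lower, RUNX2 2.01-fold and BMP2 2.003-fold. Without the probe sets that can bind several transcripts the median of the 5 genes left was -0.70, below the range.

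Cell cycle genes were slightly higher as a list, with 4 of 27 at least 2-fold higher and 0 lower. The mitotic kinases BUB1, BUB1B and AURKA were at least 2.76-fold, 2.35-fold and 2.29-fold higher, from uninduced signals of 106, 661 and 1124. These signals lay below or little above the 1028 that poly-A controls reached. In the whole list 20 genes had a ratio above 0 and 7 below, among them CENPF at -0.74, named after its value had been seen. BIRC5 was 2.35-fold higher, from an uninduced signal of 968, with probe sets down to a log2 ratio of -0.01. The median was 0.37 against a range of -0.30 to 0.22, and 0.17, inside the range, without probe sets that can bind several transcripts. Housekeeping genes had a median of 0.33 against a range of -0.36 to 0.29, with 1 of 11 higher at 2-fold. YWHAZ was 2.18-fold higher in that list and the transferrin receptor TFRC 1.64-fold. With the mean over probe sets the housekeeping median was 0.13, inside the range. As deposited, the housekeeping median was close to that of the cell cycle list. A shift of this size is therefore not particular to cell cycle genes.

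Genes of endoplasmic reticulum and oxidative stress split in 2 directions. TRIB3 and ASNS, both targets of the stress factor ATF4, were 4.21-fold and 2.79-fold lower, while the antioxidant genes HMOX1 and NQO1 were 3.19-fold and 2.55-fold higher. The median was -0.37 against a range of -0.32 to 0.24, with 2 of 16 higher and 2 lower. It was -0.05 with the mean over probe sets and 0.16 without probe sets that can bind several transcripts. The latter setting also dropped members such as ASNS. The direction of the list therefore depends on the probe sets used and the members they leave. Circadian clock genes had a median of -0.46 against a range of -0.39 to 0.28, with 1 of 13 at least 2-fold lower. NPAS2 was 3.09-fold lower, with a probe set at a log2 ratio of 0.74, and BMAL1 had a log2 ratio of -0.89. Inflammatory cytokines and chemokines went both ways, with 3 of 18 higher, 3 lower and a median of -0.11 inside the range. CXCL5 was 3.53-fold higher, PTGES 2.77-fold and SOD2 2.56-fold, and TNFAIP6 was 5.18-fold lower.

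Markers of other cell types that a stromal preparation can hold were set beside these lists. Endothelial markers were lower, with 4 of 12 at least 2-fold lower, 0 higher and a median of -0.83 against a range of -0.44 to 0.39. PECAM1, an adhesion molecule of endothelial cells, was 2.62-fold lower and the growth factor receptor KDR at least 2.18-fold. Other PECAM1 probe sets had log2 ratios up to -0.18. ERG and ROBO4 were 2.17-fold and 2.12-fold lower, but both had a probe set with a positive ratio. Macrophage and leukocyte markers had a median of -0.15, inside the range, with 2 of 10 lower. LAPTM5 was 2.11-fold lower, and LYZ 2.03-fold by its brightest probe set, against a log2 ratio of 0.06 in another. Pericyte and smooth muscle markers had a median of 0.46 against a range of -0.47 to 0.41, with 2 of 8 higher. MCAM was 3.40-fold higher, and RGS5 4.86-fold, with another RGS5 probe set at -0.57. This median was -0.05 without probe sets that can bind several transcripts, and inside the range under 4 further settings.

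**Figure D2:**
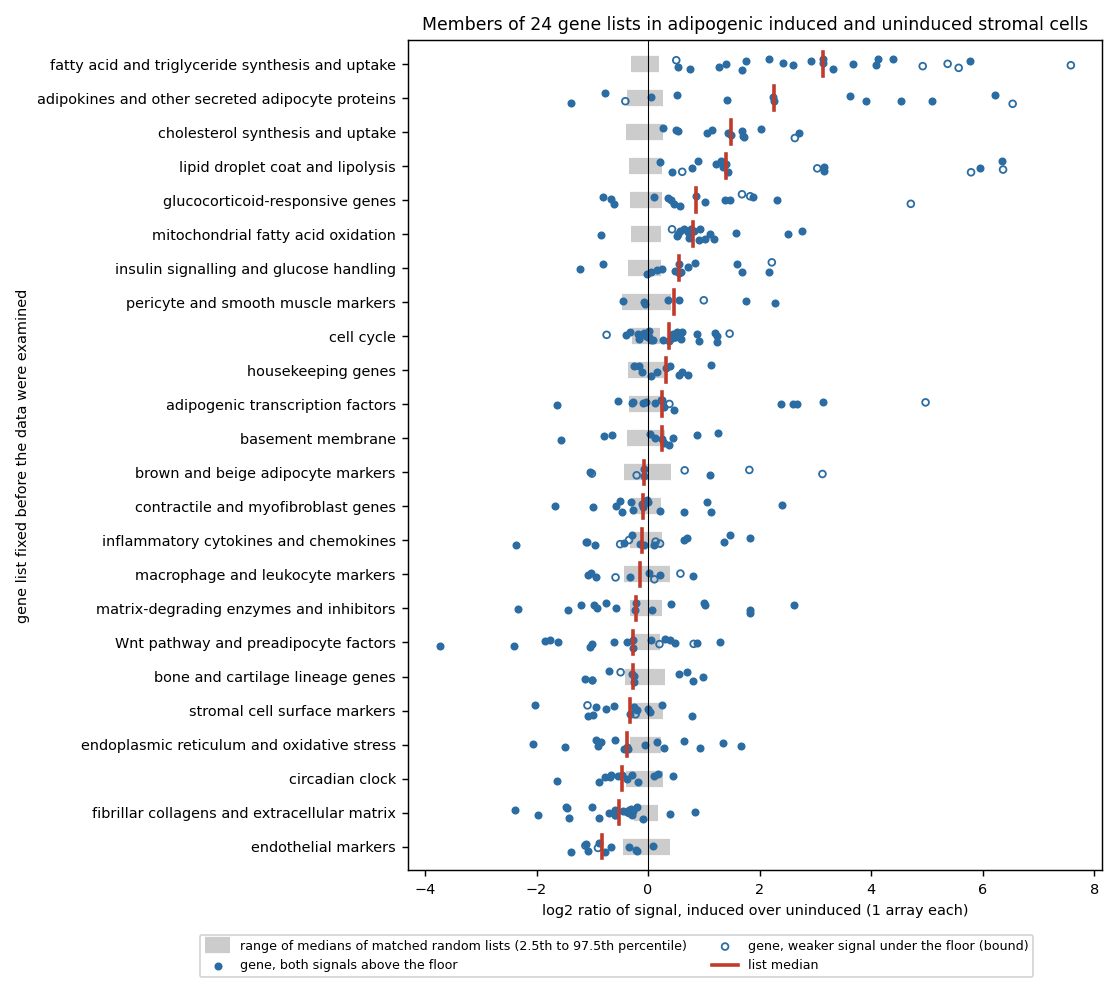
Log2 ratio of signal, induced over uninduced, for the measured members of the 24 lists, with 1 circle per gene, open where the weaker signal lay under the floor, a red bar at each list's median and a grey band for the range of medians of matched random lists. The list of fatty acid and triglyceride synthesis and uptake lies farthest to the right, with a median of 3.13, and the endothelial markers farthest to the left, at -0.83.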

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

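Most tests in this part were set before their values were seen. Chosen afterwards were the question of donors or cultures, a repeat of the endothelial markers' comparison with lists matched on signal, the rule that a test leaves an explanation open where the settings disagree, and the reading of medians inside the range and of the mitosis test given below. The rule on settings moved 3 verdicts from what the main setting alone would have given. A margin of 0.05 beyond the range, added to the scaling tests after their values were seen and prompted by a misread range, was withdrawn. With it the test would have left scaling open for the stress list. Without it the criterion set beforehand counts against scaling for each list. The reading below, that the scaling tests decide little, was chosen afterwards.

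Some signals outside the named genes were higher in the induced array, in data that the comparisons of gene lists do not use. The 5' control probe set for 28S ribosomal RNA had a log2 ratio of 1.71, while the middle one had 0.43, the 3' one lay under the floor in both arrays and the 3 control probe sets for 18S ribosomal RNA had -0.24, -0.19 and 0.25. Among 11721 probe sets without a gene name here, 4610 were above the floor in at least 1 array, of which 175 were at least 2-fold higher and 270 at least 2-fold lower.

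The cell cycle list was higher in the induced array, with a median log2 ratio of 0.37. The test of scaling decides little: the median nearest 0 under 3 other scalings was 0.365, above its range each time. Median centring moves list and range alike, and quantile normalization and loess move genes of similar signal nearly alike. The test could therefore hardly have come out in favour of scaling. The choice of members stays open: 28 further mitosis genes had a median of 0.383, above the range in 10 of 10 settings, but the list also holds replication genes, and 25 further ones had a median of 0.054, inside the range in all 10. The criterion set beforehand named mitosis genes alone and would have argued against this explanation, and the list itself came inside the range, at 0.17, without probe sets that can bind several transcripts. A difference between donors or cultures rather than induction stays open too, because there is 1 array per group. Noise of weak signals was not tested for this list. Housekeeping genes, with a median of 0.33, also lay above their range, so a shift of this size is not particular to cell cycle genes.

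The endothelial markers were lower in the induced array. The test of scaling decides little here too: the median nearest 0 under 3 other scalings was -0.772, and each median lay below its own range. Each scaling moves list and range alike or nearly so, which left the outcome almost fixed. The noise of weak signals stays open: a test on brighter members found only 2, and the median of -0.832 against lists matched on signal repeats the comparison that showed the pattern. Fewer endothelial cells may be a source: 14 measured genes of a further endothelial list had a median of -0.475, below the range, but this held in 7 of 10 settings, with -0.409, -0.283 and -0.375 inside the range under the lower floor, the higher floor and with both signals above the floor. The main setting alone would have counted in favour of this explanation, and VWF, at -0.22, and lower expression per cell leave it open too.

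The list of endoplasmic reticulum and oxidative stress was lower in the main setting, with 10 of 16 members below 0. That direction depends on the probe sets used and the members they leave. The median came inside the range with the mean over probe sets, and its sign reversed without probe sets that can bind several transcripts. The test of scaling again decides little. The median stayed below its own range under 3 other scalings, by a small distance, with -0.312 nearest 0 under median centring. Each scaling moves list and range alike or nearly so. A lower protein folding response stays open, since 16 further folding genes had a median of -0.168 inside the range with 11 lower and 5 higher, which decides nothing, though the criterion set beforehand would have argued against it. Lower ATF4 target genes may account for part of the pattern. Of these, 24 further ones had a median of -0.772, below the range in 10 of 10 settings, with 22 lower and 8 of them at least 2-fold. The test was set as one of a lower amino acid response, but it measured ATF4 targets alone. It therefore cannot tell that response from other sources of lower ATF4 targets. Differences between donors or cultures were not tested.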

How the results depend on the processing

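Counting members under the floor as 0 was chosen after the data were seen; the other alternatives were set before. Of 240 list medians under the alternatives, 215 kept their place, 15 came inside the range, 8 left it and 2 reversed, and 15 of 24 lists kept their place throughout. Of 841 values of named genes, 766 moved by less than the spread between probe sets, 73 by more and 2 reversed. The cause of these differences was not tested, apart from the counts, which follow from the size limit or from weak signals let in. Without the floor 1346 genes were higher and 1352 lower; 1773 were higher and 2122 lower with a limit of 1.5-fold, and 145 and 49 with a limit of 4-fold. Median centring, which subtracts the median ratio of -0.06 and so moves every ratio up, made 57.0% of called genes higher, against 50.5% as deposited.

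The median of adipogenic transcription factors came inside the range at 0.232 with quantile normalization, 0.257 with the lower floor, 0.244 with the higher floor, 0.257 without a floor, 0.231 with both signals above the floor and 0.275 without probe sets that can bind several transcripts. Stromal surface markers went below it at -0.296 with loess, -0.610 with the lower floor, -0.374 with the higher floor and -0.610 without a floor. Wnt and preadipocyte factors did so at -0.321 with the higher floor, -0.370 with both signals above the floor and -0.334 with the mean over probe sets. Pericyte markers came inside at 0.356 with the lower floor, 0.363 with the higher floor, 0.356 with both signals above the floor and 0.178 with members under the floor as 0. The mean over probe sets brought the stress list to -0.047 and housekeeping genes to 0.132. Without probe sets that can bind several transcripts, insulin signalling stood at 0.245, the cell cycle at 0.173 and housekeeping genes at 0.125, all inside, bone and cartilage genes at -0.698, below, and the stress list reversed to 0.161, pericyte markers to -0.051, IDI1 to -0.630 and LYZ to 0.063. No paired analysis was possible because each group has 1 array. Signal over background limits the weak genes, for which a fold is a bound.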

Other observations

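The lists in this part were written after the fixed lists had been examined but before their own values were seen, and the single genes after theirs were seen. The rules that leave a list undecided, where the settings disagree or where a median inside the range rests on members that go both ways, were chosen after the values were seen.

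In the tricarboxylic acid cycle 6 of 19 measured genes were at least 2-fold higher and 0 lower, and the median log2 ratio was 0.485, above the range in 10 of 10 settings. DLAT, a subunit of pyruvate dehydrogenase, had a log2 ratio of 2.91 and pyruvate carboxylase, PC, of 2.74. The list holds both, but they act on pyruvate ahead of the cycle and are not enzymes of the cycle itself. Peroxisome genes had a median of 0.488, also above the range in 10 of 10 settings, with 3 of 22 at least 2-fold higher, among them PXMP4 at 1.09. Branched-chain amino acid breakdown had a median of 0.342, above the range in 9 of 10 settings, with 0.223 inside it once probe sets that can bind several transcripts were removed, so that list is left undecided. BCKDHB was at 1.41 and MCCC1 at 1.33.

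Outside all lists, some of the next highest and lowest ratios are named here. The droplet-associated lectin LGALS12 was at least 39.1-fold higher, the BMP antagonist CHRDL1 35.4-fold, the alcohol dehydrogenase ADH1B 29.9-fold, the kinase subunit PRKAR2B 25.7-fold and ADIRF 25.4-fold. KLB, the co-receptor for endocrine fibroblast growth factors, was at least 17.3-fold higher and the glycerol channel AQP3 at least 13.5-fold. On the lower side stood the Wnt modulator DACT1, 6.81-fold, the chemokine CCL11, 6.54-fold, PAMR1, 6.07-fold, the planar polarity gene PRICKLE1, 5.35-fold, LRRC15, 4.77-fold, and the heparan sulfatase SULF1, 4.66-fold.

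Other lists gave no decision. Further DNA replication genes had a median of 0.054, inside the range in all 10 settings, with 16 of 25 above 0 and 9 below, which leaves higher replication genes undecided; the difference from the mitosis genes was not tested. Interferon-stimulated genes had a median of -0.296, inside the range, which ran from -0.31 to 0.22 as deposited, in 9 of 10 settings and below it with the mean over probe sets, so a lower interferon response is left undecided. The main setting alone would have counted in favour of branched-chain amino acid breakdown and against the replication and interferon lists.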
